A study of Danio rerio with 16 samples.

How the data were processed

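RNA was sequenced from wild-type zebrafish of the AB strain at 5 stages or body parts. The groups were embryos at 24 hours post fertilization (hpf), a pool of embryos labelled 16-36 hpf, larvae at 5 days, the adult head and the adult tail. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with Illumina's TruSeq RNA kit. The series holds 16 sample records. The 12 records of the 24 hpf group belong to 3 biological samples with 4 records each, which per the labels are technical runs and read ends. Files came with 1 record of each of the 3 samples and with the 4 records of the other groups, so 7 libraries were analysed and 9 records without a file were not used here. Whether the file of a 24 hpf sample pools its technical runs is not given in the sources used here. Technical runs were never treated as replicates. The age of the pool differs between its labels: 16 to 36 hours in the title, and 16 somites to 24 hpf in the stage label. It is called the 16-36 hpf pool here.

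The reads were processed with CASAVA 1.4, TopHat 1.4.1, Bowtie 0.12.7, HTSeq 0.5.3p3 and Cufflinks 1.3.0 on the Zv9 genome, per the submitters' processing notes, which give no settings. The authors deposited, per library, a table of raw counts per gene that ends in HTSeq's 5 special counters, and a table of FPKM per gene made with Cufflinks per the file headers. The annotation release and the strand setting of the counting are not given in the sources used here. The 24 hpf files list 28491 genes and the other 4 files list 32313, of which 28364 gene IDs are shared, 127 occur only in the 24 hpf files and 3949 only in the others. Of the shared IDs, 16566 have the same start and end in both, and 89 IDs have more than 1 locus. The annotation therefore differs along every comparison with 24 hpf, and so do sequencing depth and possibly the batch, which the labels do not give. For the pool these cannot be told apart from stage. Larva, head and tail were also set against the pool, which shares their annotation and has a similar depth, without a test. Chromosome, start and end are given on Zv9 as in the FPKM files. Symbols are those in the files, and 18363 of the shared IDs were also matched in a table of gene names. Genes in paralogue families (opsins, crystallins, globins, keratins, proteases, Hox clusters) and overlapping or antisense genes are uncertain, because the counting could split or drop shared reads.

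Reads counted on genes came to 41607139, 40899061 and 44962951 in the 3 libraries of 24 hpf, 11045403 in the pool, 8532429 in the larva, 8017208 in the head and 8376307 in the tail. Shared genes held 99.9% of this total in each 24 hpf library, 98.5% in the pool, 98.6% in the larva, 96.5% in the head and 93.5% in the tail. Reads without a unique alignment made up 21.1%, 14.2% and 27.6% of the counter totals at 24 hpf, 23.4% in the pool, 24.9% in the larva, 30.2% in the head and 39.6% in the tail. Reads on no gene ranged from 6.59% in the tail to 13.7% in the head, and ambiguous reads from 0.733% to 1.90%. These counters were left out of library sizes and tests. A gene at 0 counts was given an upper limit of 3 counts in that library, which is 0.273 CPM (normalised read count, scaled to a common library size as described for the test) in the pool, 0.304 in the larva, 0.314 in the head and 0.337 in the tail, or 3 counts over the 3 libraries of 24 hpf together, which is 0.0279 CPM. Such limits and the exact 95% counting intervals of ratios cover counting error only.

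Differential expression was tested on the deposited counts of shared genes with edgeR 4.0.16 in R 4.3.3. Trimmed mean of M values (TMM) factors were 0.860, 0.887 and 0.789 for the 24 hpf libraries, 1.01 for the pool, 1.17 for the larva, 1.23 for the head and 1.14 for the tail, and CPM are scaled by them. Of 24559 shared genes with a count, 21128 passed filterByExpr with a minimum count of 10. A single quasi-likelihood model with 5 groups was fitted (glmQLFit, glmQLFTest), and each of the 4 other groups was compared with 24 hpf. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as higher or lower. The SE given with a log2 change is the size of that change divided by the square root of its quasi-likelihood F statistic. It is derived from the test, and for genes of few counts it can be smaller than the counting error. Only the 24 hpf group has replicates, so the model has 2 residual degrees of freedom, the p-values measure the spread between these 3 samples, and the lone library of each other group is assumed to vary like them. The model was tested on simulated data with 200 genes changed in counts drawn from the means of the 24 hpf libraries. For the pool it recovered 2.99%, 68.7% and 93.9% of the genes changed 2-fold, 4-fold and 8-fold, with 7 false calls among 18017 genes. For the larva it recovered 7.46%, 64.2% and 93.9% with 1 false call among 17872 genes, for the head 8.96%, 71.6% and 92.4% with 8 among 17892, and for the tail 2.99%, 70.1% and 98.5% with 2 among 17961. In these simulations 2-fold changes were thus mostly not recovered. Single libraries were simulated with the spread estimated in the same data. Data with more than 200 changed genes were not simulated. For both reasons these shares may not hold for the real contrasts.

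Larva and pool, head and tail, and both adult parts and larva were compared without a test, since each has 1 library, so these differences have no replicate check. A gene was counted when it was at least 4-fold apart in CPM with 0.5 CPM added to both and at least 5 CPM in the higher library; for both adult parts, the same had to hold in head and in tail. In 10 simulations without any difference this rule counted on average 17.2 genes for larva and pool and 21.2 for head and tail. The highest counts were 24 and 28. The simulated spread was estimated in the same data. By this rule the 3 pairs of real 24 hpf libraries, which are deeper, had 23, 75 and 103 genes. A gene was called enriched in a condition at 5 CPM or more and at least 8-fold above every library of the other conditions, with the pool and 24 hpf libraries together as embryo.

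Tissue and process lists were fixed from textbook knowledge before the data were examined, as were the tests, the thresholds, the rule for named genes and the alternatives other than those stated as added. The 34 lists hold 1047 entries, of which 938 matched 951 genes of the files by symbol. For each contrast with 24 hpf, the lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over all 136 pairs of list and contrast. Camera with an estimated correlation and fry were run beside it. None of the 81 calls made with the preset correlation held with an estimated correlation, so that adjusted p stands beside each described list. Fry, which asks whether the genes of a list move one way without comparing them with other genes, called 55 of the 136, and counted in either direction (mixed) it called 26 lists for the pool, 33 for the larva, 34 for the head and 33 for the tail. List medians take genes at 0 in a group at the limit of 3 counts, and at 0 change where both groups hold 3 counts or fewer. For single libraries, the percentile of the list median among 10000 random lists of the same size, matched on mean CPM in 20 bins, is given as a description. With library totals in place of TMM, the median log2 ratio to 24 hpf of all tested genes was 0.16 for the pool, 0.44 for the larva, 0.53 for the head and 0.30 for the tail, against -0.08, -0.02, -0.01 and -0.11 with TMM, so changes are relative to a scaling that could differ by that much.

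Named genes follow a fixed rule. For each contrast with 24 hpf they are the 10 largest fold changes up and down among called genes with a proper symbol, at least 20 CPM in the higher group and all 3 ratios on the same side. For comparisons of single libraries they are the 10 largest ratios each way at 20 CPM, for enriched genes the 6 with the highest CPM per condition, and for each described list up to 4 members with the largest change in the direction of the list's median at 5 CPM or more, besides members against it. The 5 genes of highest CPM per condition were also named. After seeing the data, a selection was added of genes with the same interval in both annotations, which for larva, head and tail also lie at least 2-fold on the same side of the pool. Genes with 0 counts in a group are given as at least N-fold apart, and genes with 1 to 3 counts as a ratio with its exact counting interval. A few further genes, named as such, were chosen after their values were seen. A single gene of those picked by this rule is not reported here.

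Alternatives were RLE size factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a minimum count of 50, only the 2 groups compared, leaving out each 24 hpf library, glmTreat against a 2-fold change, the older quasi-likelihood method and, for larva, head and tail, the pool joined to the 24 hpf group or a further 2-fold distance from the pool. The size rule was varied in fold, added CPM, floor, scaling, FPKM in place of CPM and the set of genes. Genes with the same interval in both annotations were refitted as an alternative added after seeing the data. Other splits of the samples were not used here, because no comparison has 3 libraries on both sides. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, intervals and plots.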

Results

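Gene expression was measured by RNA sequencing in wild-type zebrafish over development and in adult body parts. The 7 libraries fall into 5 groups: 3 biological samples of whole embryos at 24 hpf, and 1 library each of a 16-36 hpf embryo pool, whole larvae at 5 days, the entire adult head and the entire adult tail. Values at 24 hpf are means ± SD in CPM over n = 3, and all other values come from 1 library without replicates. The counts on genes ranged from 40899061 to 44962951 at 24 hpf and from 8017208 to 11045403 in the other 4 libraries. By title the series concerns development and homeostasis, so each group was compared with the replicated 24 hpf embryos, and the single libraries were compared with each other by size of difference.

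The most abundant transcripts differed by group. The keratin gene krt4 stood at 17822 ± 1339 CPM at 24 hpf, 21922 in the pool and 12564 in the larva, against 4062 in the head and 851 in the tail. The muscle actin gene actc1b reached 21009 CPM in the larva against 5992 ± 1768 at 24 hpf, and the muscle myosin light chain gene mylz2 7969 CPM. The keratin gene krt5 reached 15134 CPM in the head. The vitellogenin gene vtg2, which codes for a yolk protein precursor, reached 14052 CPM in the tail, and the muscle creatine kinase gene ckmb 4703. The translation factor gene eef2b lay at 10346 ± 1006 CPM at 24 hpf and 10553 in the pool. The mitochondrial gene mt-co1 was among the 5 highest in every group except the pool, where it held 3847 CPM against 12134 ± 1155 at 24 hpf.

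The 3 libraries of 24 hpf had a median coefficient of variation of 16.1% over 12361 genes with a mean of 5 CPM or more, and 334 of these exceeded 50%. Their pairwise Pearson correlations across genes were 0.988, 0.981 and 0.979 on log2 CPM. The pool correlated with them at 0.915 to 0.922, the larva at 0.740 to 0.746, the head at 0.585 to 0.596 and the tail at 0.656 to 0.676. With the pool, which shares their annotation, the larva correlated at 0.856, the head at 0.687 and the tail at 0.678. Head and tail correlated at 0.612, and the larva at 0.854 with the head and 0.628 with the tail. These are correlations across genes, which are not independent replicates.

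In the 16-36 hpf pool, camera placed the lists of fast skeletal muscle, connective tissue, cartilage and bone, neurons and lens higher than at 24 hpf and the hatching gland lower, with under 50% of the members of each higher list past the gene test. None of these 6 calls held with an estimated correlation (camera adjusted p = 0.578 for each). Among the largest increases at 20 CPM or more was matn3a (matrilin 3a, a cartilage matrix protein; ENSDARG00000069245, Zv9 chromosome 20, 43791821 to 43807307), at 22.02 CPM against 0.205 ± 0.191. Another was ank2 (ankyrin 2, a membrane skeleton adaptor; ENSDARG00000043313, chromosome 7, 59131812 to 59343896), at 119 against 1.49 ± 0.543. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their log2 changes were 6.71 (SE 0.54, adjusted p = 0.00219) and 6.32 (SE 0.36, adjusted p = 0.00106). Muscle genes among the largest increases were ampd1, coding for AMP deaminase, with a log2 change of 6.53, the calcium pump gene atp2a1l with 5.97, the calcium release channel gene ryr3 with 4.78 and the actin-binding gene xirp2a with 4.48. The actinodin genes and3 and and2, which code for structural proteins of the fin fold, rose by 4.99 and 4.76. The collagen genes col17a1a and COL19A1 rose by 5.20 and 4.66. The adjusted p of these 8 genes ranged from 0.00106 to 0.0105 in edgeR's quasi-likelihood test. Genes with the same interval in both annotations included atp2a1l, and2, COL19A1, the actinodin gene and1 (177 against 16.9 ± 9.14 CPM) and the neurofilament gene NEFM (1 of 2) (33.2 against 2.89 ± 1.98). The intervals of matn3a, ank2, ampd1, ryr3, xirp2a, and3 and col17a1a differed between the annotations. For these genes a change of the annotated gene and a change with stage cannot be told apart. For genes with the same interval, changes within it were not compared.

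The neuron and synapse list had 20 of 58 tested members higher and none lower, among them the vesicle genes SV2A and slc17a6a. The gad2 gene, which codes for an enzyme of GABA synthesis, stood at 20.2 against 3.16 ± 0.732 CPM. Adjusted over the list alone, 25 were higher. Its median log2 change was 1.01 (camera adjusted p = 1.53e-08, and adjusted p = 0.578 with an estimated correlation). Fast skeletal muscle had 11 of 38 higher and none lower (16 adjusted over the list alone). Examples are the titin gene ttna at 1097 against 49.8 ± 11.7 CPM and the parvalbumin gene pvalb1 at 711 against 93.3 ± 53.5. Camera gave an adjusted p of 2.36e-08, and an adjusted p = 0.578 with an estimated correlation. Lens crystallins had 22 of 59 higher, with crygm2d15 at 7.83 against 0.0657 CPM, and 1 lower, crygm4, at 0.273 against 17.9 CPM. Adjusted over the list alone, 34 were higher and 2 lower (camera adjusted p = 5.93e-08, and adjusted p = 0.578 with an estimated correlation). Collagens and connective tissue had 6 of 30 higher, including col6a1 and col6a3, and none lower. Cartilage and bone had 6 of 34 higher, including hapln1a and sox9a, and none lower. Adjusted over the list alone, 7 were higher in each list. Their camera adjusted p values were 4.33e-04 and 0.00158, and adjusted p = 0.578 for both with an estimated correlation.

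The hatching gland, whose proteases digest the egg envelope, had 4 of 8 genes lower and none higher (5 lower adjusted over the list alone). Its median log2 change was -2.24 (camera adjusted p = 0.0114, and adjusted p = 0.578 with an estimated correlation). The protease genes ctsl1b and he2 fell from 1054 ± 396 to 98.4 CPM and from 141 ± 29.2 to 15.11 CPM. For he1a (ENSDARG00000023656, chromosome 22, 14237423 to 14238861), the difference between 1134 ± 600.3 and 168 CPM did not pass edgeR's quasi-likelihood test (adjusted p = 0.0551). The myogenic regulator gene myog fell from 95.3 ± 16.4 to 14.7 CPM. In the list of muscle specification, 3 of 16 members were lower and 1 was higher, and in slow muscle 3 of 14 were lower and 2 higher (camera adjusted p = 0.849 and 0.862). Heart muscle had 2 of 16 lower and 1 higher (camera adjusted p = 0.959). Of the 13 mitochondrially encoded genes, 0 passed the gene test and 8 were lower adjusted over the list alone. Camera placed that list lower with a median of -0.99 (adjusted p = 1.22e-04, and adjusted p = 0.451 with an estimated correlation). Camera also placed lower the vitellogenin and egg coat genes (1 of 24 lower, adjusted p = 0.00540), middle Hox (1 of 12 lower, hoxb8b, adjusted p = 0.0180), posterior Hox (1 of 22 lower, hoxc10a, adjusted p = 0.0245) and epidermis (5 of 34 lower and 2 higher, adjusted p = 0.0449). With an estimated correlation these 4 had adjusted p = 0.546, 0.589, 0.621 and 0.578 in camera. Of the 11 lists that camera called for the pool, limma's fry called 1, the mitochondrially encoded genes (adjusted p = 0.0314).

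The 10 named genes with the largest decreases in the pool were at or near 0 counts there. One of them was foxd3, a transcription factor of the neural crest (ENSDARG00000021032, chromosome 6, 31784201 to 31786000), at 52.04 ± 5.63 CPM at 24 hpf and at least 191-fold lower in the pool. RAC1 (3 of 6) was at least 337-fold lower from 92.1 ± 7.51 CPM. The chaperone gene ppid (ENSDARG00000038835, chromosome 14, 51150478 to 51153666) was at least 216-fold lower from 58.9 ± 2.06 CPM. All 3 also had 0 counts in the larva, head and tail, but the deposited FPKM of ppid in the pool was 35.8 and that of foxd3 in the larva 5.56. DEPDC7 (2 of 2) fell from 859 ± 71.1 to 0.273 CPM, a ratio of 3146 (exact 95% counting interval 1076 to 15254). Among genes with the same interval in both annotations, the selenoprotein gene seph fell from 199.98 ± 37.5 to 2.00 CPM. The SUMO protease gene senp3b fell from 1434 ± 84.9 to 41.4. Both were also low in larva, head and tail, at 2.81 CPM or less for seph and 89.6 or less for senp3b. Changes within an interval were not compared, so for these genes too annotation and stage cannot be told apart.

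In total, 2509 of 21128 genes differed between the pool and 24 hpf in edgeR's quasi-likelihood test, 1336 higher and 1173 lower. Scaled by library totals only, 1936 were higher and 667 lower. The balance turned in DESeq2 (1280.0 higher, 1423 lower), without sample 3 of 24 hpf (1979 and 2357) and on genes with the same interval, added after seeing the data (397 and 524). The count depends on the 24 hpf samples: without sample 1, 2 or 3 it was 179, 160 or 4336. Limma-voom called 3 genes (5918 at an unadjusted p under 0.05) and DESeq2 2703. Stage, annotation and depth cannot be told apart for the pool, and 1091 of the called genes have the same interval in both annotations.

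**Figure D1:**
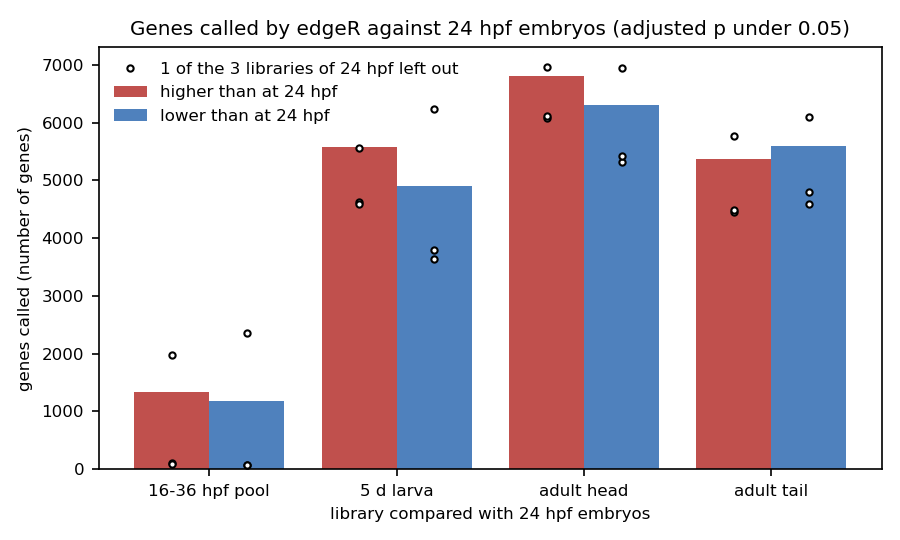
Number of genes (vertical axis) higher (red bars) and lower (blue bars) than at 24 hpf in each of the 4 other groups (horizontal axis), at an edgeR quasi-likelihood adjusted p under 0.05 among 21128 tested, with points for the counts when 1 of the 3 libraries of 24 hpf is left out. The pool has 1336 higher and 1173 lower, the head has 6816 and 6300, and for the pool the points range from 160 to 4336 in total.

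At 5 days, larvae had far higher levels of genes of photoreceptors, exocrine pancreas, intestine and neurons than 24 hpf embryos, and lower levels of genes of the cell cycle, somite formation and neural progenitors. The ultraviolet opsin gene opn1sw1 (ENSDARG00000045677, chromosome 4, 12642188 to 12644872) was at 1264 CPM with no count at 24 hpf, at least 45252-fold higher. The rod opsin gene rho (ENSDARG00000002193, chromosome 8, 55706884 to 55708411) was at 969 CPM against 3 counts in all 24 hpf libraries, a ratio of 34686 (exact 95% counting interval 11865 to 168226). The chymotrypsinogen gene ctrb1 (ENSDARG00000090428, chromosome 7, 36522726 to 36533247) was at 285 CPM against 1 count, a ratio of 30598 (5487 to 1208972). The myelin basic protein gene mbp was at least 2279.8-fold higher, and the carboxypeptidase gene cpa5 was at 204 CPM. The red opsin gene opn1lw2 rose by 12.72 on the log2 scale (SE 0.36, adjusted p = 2.59e-06 in edgeR's quasi-likelihood test). It had 7 counts at 24 hpf, and the exact counting interval of its ratio, 3565 to 18292, is wider than this SE implies. The hypertrophic cartilage collagen gene col10a1 rose by 11.79. Among genes with the same interval in both annotations and also higher than in the pool were rho, the chitinase gene chia.3 (137 against 0.131 ± 0.0655 CPM), the cone phosphodiesterase gene pde6h (255 against 0.355 ± 0.1199), the myosin heavy chain gene myhb (207 against 0.316 ± 0.0821) and atp2a1l (1053 against 1.95 ± 1.38).

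Photoreceptor genes were higher for 43 of 46 tested members with none lower, with opn1mw1 at 364 CPM. Their median log2 change was 6.23 (camera adjusted p = 4.34e-18, and adjusted p = 0.385 with an estimated correlation). Neurons and synapse had 55 of 58 higher and none lower (56 higher adjusted over the list alone). The glutamate receptor gene grin1b rose from 0.505 ± 0.327 to 174 CPM and the synaptic gene nrgna by 6.22 on the log2 scale. Camera gave an adjusted p of 1.10e-15, and an adjusted p = 0.522 with an estimated correlation. Exocrine pancreas had 22 of 24 higher and 1 lower, ctssb.1, with the elastase gene ela3l at 124 CPM and the trypsin gene try at 575. The median was 8.33 (camera adjusted p = 1.54e-11, and adjusted p = 0.385 with an estimated correlation). Intestine had 25 of 31 higher, including the vil1l gene with a log2 change of 8.82, and 2 lower (camera adjusted p = 1.39e-07, and adjusted p = 0.470 with an estimated correlation). Lens crystallins had 43 of 59 higher and 2 lower, fast muscle 27 of 38 higher and collagens 18 of 30. Cartilage and bone had 16 of 34 higher and 1 lower, and matn1 (matrilin 1; ENSDARG00000030215, chromosome 19, 45245319 to 45268900) stood at 430.2 against 0.270 ± 0.115 CPM. The camera adjusted p values of these 4 lists were 1.95e-08, 3.47e-06, 1.37e-05 and 6.45e-04, and adjusted p = 0.578 for each with an estimated correlation. Adjusted over the list alone, 44 crystallins were higher and 3 lower, and 20 collagens were higher. Pituitary and hypothalamic hormones had 14 of 28 higher, including pomca and vip, and olfactory and gill genes 10 of 18 higher and 1 lower. Liver and plasma proteins had 17 of 44 higher and 4 lower, with fabp10a rising from 0.398 to 108 CPM. Camera gave adjusted p values of 0.00124, 0.00977 and 0.0419, and adjusted p = 0.470, 0.470 and 0.726 with an estimated correlation.

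Of the cell cycle and DNA replication list, 39 of 44 genes were lower in the larva and none higher (41 lower adjusted over the list alone). Their median was -2.61 (camera adjusted p = 1.31e-12, and adjusted p = 0.470 with an estimated correlation). The helicase subunit gene mcm3 fell from 107 to 3.44 CPM and the ribonucleotide reductase gene rrm2 by 5.35 on the log2 scale. Neural progenitor genes were lower for 26 of 38 and higher for 1, and on the log2 scale sox19a fell by 3.75 and dbx1b fell by 3.88. Somite and paraxial mesoderm genes were lower for 20 of 27, with cdx4 falling by 5.88 and tbx16 falling by 4.53. Camera adjusted p values were 1.39e-07 and 2.81e-06, and adjusted p = 0.578 for both with an estimated correlation. With the same interval in both annotations, msgn1, a transcription factor of presomitic mesoderm, was at 20.2 ± 11.5 CPM at 24 hpf and 14.7 in the pool against 1 count in the larva. Its ratio of 24 hpf to larva was 199.8 (exact counting interval 35.8 to 7897). The Hes-type repressor gene her15.2 fell by 6.85 on the log2 scale. Posterior, middle and anterior Hox genes were lower for 13 of 22, 6 of 12 and 10 of 14 (camera adjusted p = 3.88e-05, 0.0247 and 7.06e-04, and adjusted p = 0.578, 0.610 and 0.470 with an estimated correlation). Embryonic globins were lower for 9 of 11, with hbbe3 falling from 513 ± 126 to 9.11 CPM. Signalling ligands were lower for 20 of 53 with 2 higher. Hatching gland genes were lower for 6 of 8 with 1 higher, he2 being at least 465-fold lower. Their camera adjusted p values were 0.00242, 1.30e-04 and 0.00685, and adjusted p = 0.611, 0.385 and 0.578 with an estimated correlation. Muscle specification had 6 of 16 lower and 1 higher, haematopoiesis 9 of 18 and 2, egg coat 7 of 24 and 1, and epidermis 15 of 34 and 5. Camera placed these 4 lists lower with adjusted p values of 0.00933, 0.0200, 0.0458 and 0.0458. With an estimated correlation camera gave adjusted p = 0.522, 0.510, 0.578 and 0.578.

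A total of 10474 genes differed between larva and 24 hpf in edgeR's quasi-likelihood test, 5574 higher and 4900 lower, and 4746 of them have the same interval in both annotations. Scaled by library totals only, 7004 were higher and 3036 lower, and without sample 3 of 24 hpf 5567 were higher and 6243 lower. When the pool was joined to the 24 hpf group, 4352 genes were called. Of the 10474 genes, 6051 also lay at least 2-fold on the same side of the pool. In simulated data without differences at most 2 genes were called at all, and at most 1 with this distance. The simulated data held no annotation or batch difference, so they cannot show how much of the count comes from either. Each single library was also drawn with the spread estimated in the same data. A low count was thus built in, and a larger spread of a single library was not tested.

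The adult head had higher levels of genes of vision, myelin, neurons, adaptive immunity, pituitary hormones and adult globins than 24 hpf embryos, and lower levels of genes of the cell cycle, Hox clusters and embryonic globins. The mbp gene (ENSDARG00000036186, chromosome 19, 22298343 to 22316927) stood at 1166 CPM and was at least 41742-fold higher. The rho gene was at 3809 CPM, 136344-fold above its 3 counts at 24 hpf (exact 95% counting interval 46651 to 661175). The crystallin gene crybb2 (chromosome 8, 44670178 to 44676709) was at 866 CPM, 92977-fold above 1 count (16683 to 3672838), and crygm6 was at 415 CPM with no count in any other library. The antigen presentation gene mhc2dab was at 157 CPM, at least 5624-fold higher. The vitellogenin gene vtg2 (ENSDARG00000055809, chromosome 22, 25342159 to 25353294) stood at 4695 CPM in the head against 0.215 ± 0.115, a log2 change of 14.38 (SE 0.54, adjusted p = 5.33e-06 in edgeR's quasi-likelihood test). The vitellogenin genes vtg3, vtg4 and si:rp71-23d18.1 stood at 449.9, 1103 and 685.6 CPM in the head. In the tail, vtg2, vtg3 and vtg4 stood at 14052, 1485 and 4133 CPM, and si:rp71-23d18.1 was also higher there than in the head. With the same interval in both annotations and also higher than in the pool were rho, myhb at 2915 CPM, pde6h at 1452, vtg3 and the luteinizing hormone gene lhb at 43.7.

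All 46 photoreceptor genes were higher in the head, with a median log2 change of 8.36 (camera adjusted p = 2.11e-18, and adjusted p = 0.385 with an estimated correlation). Higher were also 48 of 58 neuron and synapse genes, with 1 lower (camera adjusted p = 2.20e-11, and adjusted p = 0.567 with an estimated correlation). Adaptive immunity had 24 of 26 genes higher and 2 lower. Examples are iclp1 (invariant chain-like protein, ENSDARG00000009087, chromosome 14, 3122604 to 3136493) at 826 against 0.262 ± 0.220 CPM, cd74 at 474 against 0.474 ± 0.189 and the recombination gene rag1 at 276 against 1.06. Innate immune cells had 23 of 31 higher and 2 lower (3 adjusted over the list alone), with the leukocyte phosphatase gene ptprc at 82.4 against 1.41 CPM. Camera adjusted p values were 1.51e-07 and 1.88e-04, and adjusted p = 0.385 and 0.578 with an estimated correlation. Pituitary and hypothalamic hormones had 22 of 28 higher and 2 lower, among them the growth hormone gene gh1 at 37.4 CPM, the glycoprotein hormone alpha gene cga at 52.9 and the pro-opiomelanocortin gene pomca at 38.4. The list had a median of 3.75 (camera adjusted p = 9.48e-06, and adjusted p = 0.451 with an estimated correlation). All 3 measured adult globins were higher, with ba1 (ENSDARG00000089087, chromosome 3, 55950129 to 55955982) at 414 and hbaa1 at 453 CPM. Their camera adjusted p was 0.00704, and adjusted p = 0.470 with an estimated correlation. Glia and myelin had 12 of 21 higher and 4 lower, lens crystallins 29 of 59 higher and 3 lower, and olfactory and gill genes 11 of 18 higher and 1 lower. Their camera adjusted p values were 0.0419, 0.00124 and 0.00937, and adjusted p = 0.578, 0.726 and 0.470 with an estimated correlation. Exocrine pancreas had 20 of 24 higher and 1 lower (21 higher adjusted over the list alone), and intestine 22 of 31 higher and 5 lower (camera adjusted p = 1.95e-08 and 5.26e-04, and adjusted p = 0.385 and 0.561 with an estimated correlation). Of the epidermis list, which camera did not call, krt15 stood at 2516 against 7.18 ± 2.61 CPM. The ependymin gene epd stood at 1891 against 7.40 ± 3.96 CPM.

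All 44 tested genes of the cell cycle and DNA replication list were lower in the head, with a median of -4.71 (camera adjusted p = 4.94e-15, and adjusted p = 0.470 with an estimated correlation). On the log2 scale rrm2 fell by 6.63, and the mitotic kinase genes plk1 and aurkb fell by 5.82 and 5.64. Neural progenitor genes were lower for 32 of 38, somite genes for 24 of 27, muscle specification genes for 13 of 16 and signalling ligands for 32 of 53 with 2 higher. Their camera adjusted p values were 8.82e-10, 1.81e-06, 2.77e-04 and 5.18e-06, and adjusted p = 0.578, 0.578, 0.470 and 0.385 with an estimated correlation. Hox genes were lower for 21 of 22 posterior, 12 of 12 middle and 14 of 14 anterior members, and hoxc13a was at least 64.9-fold lower (camera adjusted p = 1.83e-08, 1.95e-05 and 5.10e-06, and adjusted p = 0.510, 0.561 and 0.385 with an estimated correlation). Embryonic globins were lower for 10 of 11 (camera adjusted p = 2.51e-05, and adjusted p = 0.578 with an estimated correlation). The hbae3 gene (ENSDARG00000079305, chromosome 3, 55998268 to 55999416) fell from 558 ± 126 to 0.210 CPM, a ratio of 2657 (exact counting interval 735 to 21937), and hbbe1.1 (ENSDARG00000089963) was at least 986-fold lower. The protease genes ctsl1b and he1b were at least 3358-fold and 1324-fold lower. Some lists split: cartilage and bone had 16 genes higher and 14 lower of 34 and fast muscle 17 higher and 13 lower of 38 (camera adjusted p = 0.737 and 0.406). The cartilage collagen gene col2a1a fell from 2084 ± 460.5 to 39.4 CPM and the myosin gene myhz1.1 from 1185 ± 538 to 38.6, while col10a1 stood at 198 CPM. Collagens had 15 of 30 higher and 5 lower, hatching gland 1 of 8 and 5, and epidermis 14 of 34 and 8. Liver had 18 of 44 higher and 13 lower, egg coat 4 of 24 and 6, and slow muscle 5 of 14 and 4. None of these 6 lists was called by camera (adjusted p = 0.0602, 0.0734, 0.295, 0.380, 0.466 and 0.736).

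In the head, 13116 genes differed from 24 hpf in edgeR's quasi-likelihood test, 6816 higher and 6300 lower, and 6010 of them have the same interval in both annotations. Scaled by library totals only, 8319 were higher and 4367 lower. A refit on the 9964 genes with the same interval called 6092. Of the 13116 genes, 9338 also lay at least 2-fold on the same side of the pool. In simulated data without differences at most 1 gene was called at all, with or without this distance. As for the larva, those data held no annotation or batch difference, and a low count was built in.

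The adult tail had higher levels of genes of the egg coat and yolk, exocrine pancreas and intestine than 24 hpf embryos, and lower levels of genes of neural progenitors, signalling ligands, neurons and Hox clusters. The vtg2 gene rose from 0.215 ± 0.115 to 14052 CPM, a log2 change of 15.96 (SE 0.56, adjusted p = 3.61e-06 in edgeR's quasi-likelihood test). The zona pellucida gene zp3.1, which codes for an egg coat protein (ENSDARG00000090768, chromosome 17, 2347490 to 2373484), rose from 8.32 ± 3.30 to 1598 CPM. Its relatives zp3a.1 and zpcx stood at 1236 and 885 CPM. The digestive lipase gene cel.2 (ENSDARG00000029822, chromosome 21, 9809056 to 9817988) stood at 1066 CPM with a log2 change of 13.54, and ctrb1 at 1169 CPM, 125556.5-fold above 1 count (exact 95% counting interval 22530.0 to 4959688). The elastase gene CELA1 (4 of 8) was at least 5603-fold higher. With the same interval in both annotations and also higher than in the pool were PATL2 at 521 CPM, KPNA7, an importin gene, at 788, zpcx, pabpc1l at 403, vtg3 at 1485 and chia.3 at 953.

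All 24 vitellogenin and egg coat genes were higher in the tail, with a median log2 change of 7.77 (camera adjusted p = 7.60e-14, and adjusted p = 0.385 with an estimated correlation). Exocrine pancreas had 23 of 24 higher and 1 lower (median 10.37), and intestine 25 of 31 higher and 2 lower (3 adjusted over the list alone), with the bile acid binding gene fabp6 at 191 CPM. Camera adjusted p values were 1.83e-13 and 1.35e-07, and adjusted p = 0.385 and 0.470 with an estimated correlation. Liver and plasma proteins had 25 of 44 higher and 9 lower, with fabp10a at 527 CPM. Adaptive immunity had 19 of 26 higher and 2 lower, innate immune cells 16 of 31 higher and 2 lower, and all 3 adult globins were higher. Their camera adjusted p values were 0.00278, 1.95e-05, 0.00469 and 0.00362, and adjusted p = 0.614, 0.385, 0.614 and 0.470 with an estimated correlation. The cell cycle list split, with 9 of 44 higher and 13 lower (camera adjusted p = 0.843). Genes that rose included the mitotic cyclin gene ccnb2 (ENSDARG00000036180, chromosome 7, 31962885 to 31967624), from 25.9 to 498 CPM, and cdc20, from 124 to 449. Genes that fell included the replication genes pcna, from 1207 to 313, and mcm6, from 408 to 17.1.

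Neural progenitor genes were lower in the tail for 36 of 38, with a median of -6.26 (camera adjusted p = 4.68e-14, and adjusted p = 0.565 with an estimated correlation). The sox1b gene (ENSDARG00000008131, chromosome 1, 46691463 to 46693213) was at 43.8 ± 4.78 CPM at 24 hpf and at least 129.8-fold lower in the tail, and neurod4 was at least 194-fold lower. Neurons and synapse had 35 of 58 lower and 5 higher, with elavl3, an RNA-binding protein of neurons, falling from 111 to 1.24 CPM (camera adjusted p = 2.19e-05, and adjusted p = 0.578 with an estimated correlation). Signalling ligands were lower for 41 of 53 and higher for 1, and somite genes lower for 19 of 27 and higher for 2 (camera adjusted p = 9.50e-10 and 2.21e-04, and adjusted p = 0.385 and 0.578 with an estimated correlation). Posterior Hox genes were lower for 20 of 22, with hoxc10a falling from 45.5 ± 2.47 to 4.27 CPM, and all 12 middle and 14 anterior Hox genes were lower. Camera adjusted p values were 1.39e-07, 6.55e-06 and 1.00e-06, and adjusted p = 0.522, 0.546 and 0.385 with an estimated correlation. Lower were also all 11 embryonic globins, hbbe3 at least 1517-fold, 15 of 16 muscle specification genes, and 14 of 18 haematopoietic genes with 1 higher (camera adjusted p = 1.72e-05, 2.85e-06 and 5.75e-04, and adjusted p = 0.578, 0.451 and 0.470 with an estimated correlation). Pigment cells had 17 of 23 lower and 2 higher, heart muscle 9 of 16 and 1, and epidermis 18 of 34 and 4. Endothelium had 13 of 24 lower and 2 higher, and olfactory and gill genes 11 of 18 and 2. Camera placed these 5 lists lower with adjusted p values of 0.00873, 0.00937, 0.0128, 0.0200 and 0.0200. With an estimated correlation camera gave adjusted p = 0.678, 0.578, 0.578, 0.679 and 0.510. Lens crystallins had 18 of 59 lower and 4 higher (15 and 2 adjusted over the list alone), and hatching gland genes 6 of 8 lower and 1 higher. Mitochondrially encoded genes had 2 of 13 lower, and 0 adjusted over the list alone. Camera placed these 3 lists lower with adjusted p values of 0.0207, 0.0273 and 0.0156, and adjusted p = 0.770, 0.578 and 0.497 with an estimated correlation. Cartilage and bone had 13 of 34 higher and 16 lower, collagens 12 of 30 and 14, and fast muscle 16 of 38 and 12. Slow muscle had 3 of 14 higher and 9 lower, photoreceptors 4 of 46 and 11, glia 5 of 21 and 11, and hormones 1 of 28 and 6. None of these 7 lists was called by camera (adjusted p = 0.455, 0.891, 0.445, 0.336, 0.336, 0.204 and 0.337).

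In the tail, 10958 genes differed from 24 hpf in edgeR's quasi-likelihood test, 5369 higher and 5589 lower, and 4876 of them have the same interval in both annotations. The balance turned when scaled by library totals only (6794 higher, 4229 lower) or by RLE (5754 and 5228), in limma-voom (4828 and 4023) and with the pool joined or a further 2-fold distance from it (3700.0 and 3195, 4132 and 3801). When the pool was joined to the 24 hpf group, 6895 genes were called. Of the 10958 genes, 7933 also lay at least 2-fold on the same side of the pool. In simulated data without differences at most 2 genes were called at all, with or without this distance. As for the larva, those data held no annotation or batch difference, and a low count was built in.

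**Figure D2:**
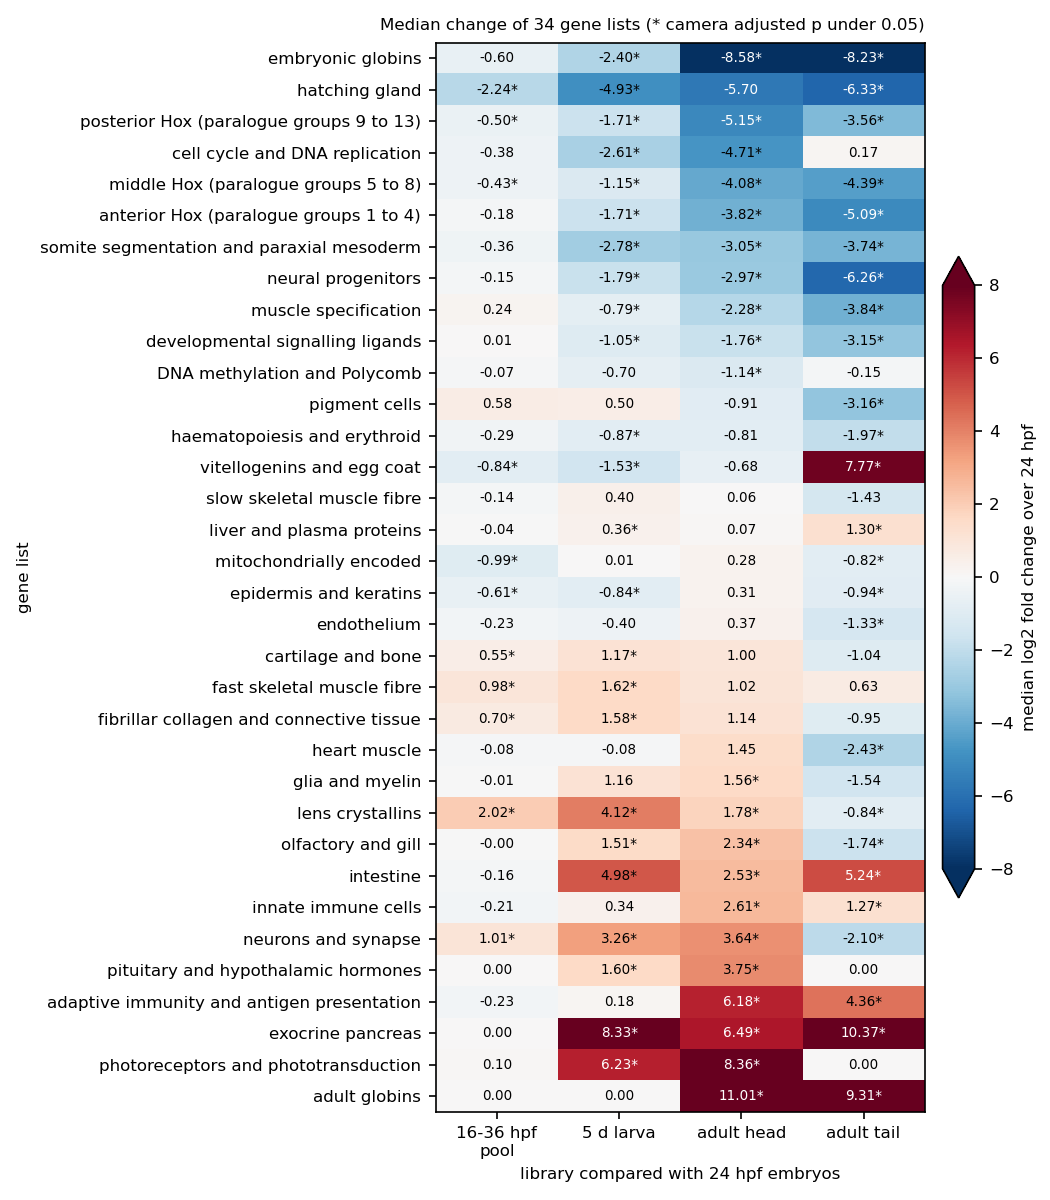
Median log2 ratio to 24 hpf of each of the 34 gene lists (vertical axis) in the pool, larva, head and tail (horizontal axis), with genes at 0 at the limit of 3 counts, a colour scale from -8 to 8, and a star for a camera adjusted p under 0.05. Photoreceptors stand at 6.23 in the larva and 8.36 in the head, and vitellogenins and egg coat at 7.77 in the tail.

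Median, mean and camera direction of a list differed in sign for some lists that camera did not call: muscle specification, slow muscle, heart, glia, olfactory and gill, haematopoiesis, signalling ligands and DNA methylation in the pool. The same held for heart in the larva, and for cell cycle and collagens in the tail. Adult globins and exocrine pancreas in the pool, adult globins in the larva and photoreceptors in the tail had a median of 0 with a negative mean, and hormones had a median of 0 with a positive mean in the pool and a negative one in the tail. In the pool, the cell cycle list had 1 of 44 genes higher and 2 lower, photoreceptors 5 of 46 and 2, and neural progenitors 2 of 38 and 2. Liver had 2 of 44 higher and 1 lower, intestine 1 of 31 and 1, innate immune cells 2 of 31 and 2, and pigment cells 1 of 23 higher. Somites, embryonic globins, endothelium and adaptive immunity had 0 genes past the test. Camera called none of these lists (adjusted p from 0.0665 to 0.779). In the larva, glia had 10 of 21 higher and 4 lower, slow muscle 6 of 14 and 3, and pigment cells 7 of 23 and 4. Innate immune cells had 9 of 31 higher and 5 lower, adaptive immunity 5 of 26 and 2, endothelium 3 of 24 and 5, and mitochondrial genes 2 of 13 higher. Camera called none of these lists either (adjusted p from 0.0764 to 0.841).

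Between larva and pool, without a replicate check, photoreceptor, pancreas, intestine and neuron genes were higher in the larva, and cell cycle and hatching gland genes were lower. The opsin genes opn1sw1 and opn1mw1 were at 1264 and 364 CPM against 0, at least 4631-fold and 1332-fold higher. The rod opsin gene rho was 665.5-fold higher (exact 95% counting interval 409.6 to 1165). The trypsin gene try was 1053-fold higher (483 to 2869.6) and matn1 788-fold (362 to 2148). The hatching gland gene ctsl1b was 97.1-fold lower (52.6 to 203), hbbe3 63.1-fold lower (51.2 to 78.6) and the RNA-binding protein gene LIN28A (2 of 2) 81.8-fold lower (31.7 to 302). Of the pancreas list 21 of 24 genes were at least 4-fold higher, of photoreceptors 35 of 46, of intestine 20 of 31 and of neurons 33 of 58, with none lower, and their medians lay at percentile 100 of random matched lists (4.57 on the log2 scale for photoreceptors and 6.785 for pancreas). Of the cell cycle list 32 of 44 were at least 4-fold lower, of hatching gland 4 of 8 and of somite genes 9 of 27, with none higher and medians at percentile 0. In total 1962 genes were at least 4-fold apart, 1519 higher and 443 lower, whereas the 3 pairs of 24 hpf libraries had 23, 75 and 103.

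Between head and tail, also without a replicate check, genes of the eye, brain and skin were higher in the head, and genes of the egg coat, cell cycle, pancreas and intestine were higher in the tail. The lens gene crygs1 (ENSDARG00000042992, chromosome 22, 11820663 to 11824256) was at 2609 CPM in the head with no count in the tail, at least 7733-fold higher, and epd was at least 5606-fold higher. The rho gene was 11291-fold higher (exact 95% counting interval 3863 to 54755), and the cone transducin gene gnat2 2462-fold (681 to 20334). In the tail, zp3a.1 was 1965-fold higher (902 to 5355), PATL2 4968-fold (891 to 196261), zp3.1 1173-fold (685 to 2203) and zpcx 1056-fold (535 to 2446). All 46 photoreceptor genes were at least 4-fold higher in the head, as were 53 of 58 neuron genes and 11 of 18 olfactory and gill genes. Of crystallins 35 of 59 were higher and 1 lower, of epidermal genes 24 of 34 and 1, and of cartilage and bone genes 18 of 34 and 1. The medians of these 6 lists lay at percentile 100. The egg coat list had 19 of 24 genes at least 4-fold lower in the head, the cell cycle list 40 of 44, pancreas 22 of 24 and intestine 17 of 31, with none higher and medians at percentile 0. In posterior Hox genes none of 22 was 4-fold apart, with a median log2 ratio of -0.93 at percentile 0. In total 5421 genes were at least 4-fold apart, 3060 higher in the head and 2361 higher in the tail. The balance turned with a floor of 20 CPM (1681 and 1900.0) and was near level in FPKM (2039 and 2022).

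**Figure D3:**
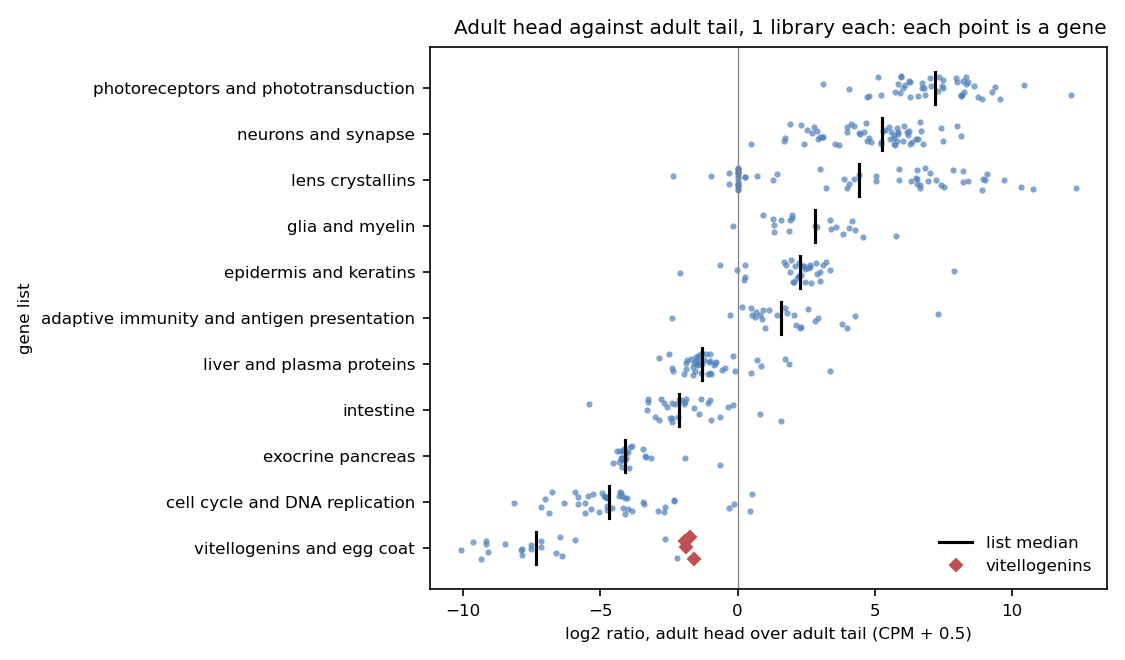
Log2 ratio of head over tail in CPM with 0.5 added (horizontal axis), 1 point per gene in 11 gene lists (vertical axis), with a black bar at each list's median and red diamonds for the 4 vitellogenin genes. The photoreceptor median is 7.198 and the egg coat median -7.34, while the 4 vitellogenins lie near -1.79.

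Both adult parts differed from the larva by at least 4-fold in the same direction for 543 genes, 185 higher and 358 lower. The vitellogenin genes vtg2 and vtg3 were 12992-fold (exact 95% counting interval 6305 to 32315) and 1875-fold (803 to 5776) higher over both parts. The adult globin genes hbaa1 and ba1 were at least 994-fold and 873-fold higher, and the antigen presentation genes iclp1 and b2m 861-fold (395 to 2346) and 248-fold (153 to 435) higher. The fin fold gene and2 was 8276-fold lower (1485 to 326954), the embryonic globin gene hbae3 1666-fold lower (650.2 to 6119), myhz1.1 171-fold lower (154 to 189) and col2a1a 132-fold lower (120.1 to 146). All 3 adult globins, 13 of 26 adaptive immunity genes and 4 of 24 vitellogenin and egg coat genes were higher, with none lower. Their medians, taken over the mean of each gene's head and tail log2 ratios to the larva, lay at percentile 100. Of the egg coat list, 19 of 24 genes were at least 4-fold lower in head than tail. Its median thus does not show a rise in both parts. Lower were 9 of 11 embryonic globins, 24 of 59 crystallins, 14 of 34 cartilage and bone genes with 1 higher and 14 of 38 fast muscle genes with 1 higher, with medians at percentile 0.

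A total of 530 genes were enriched at least 8-fold in 1 condition over all others: 43 in the embryo, 14 in the larva, 121 in the head and 352 in the tail. Those of the embryo with the highest CPM were the troponin gene tnnt2c (548 ± 31.9 at 24 hpf and 387 in the pool), hbbe3, the neural progenitor genes sox3 and sox19a, he1a and the Notch ligand gene dld. In the larva they were matn1, the crystallin genes crygm2d13, crygm2d7, crygm2d11 and crygm2d14, and fbp2, a gluconeogenic enzyme, at 62.4 CPM. In the head they were myhb, crygs1, krt15, epd, mbp and the hemidesmosome integrin gene itgb4 at 1279 CPM. In the tail they were zp3.1, zp3a.1, retsatl at 1331, cpb1, a carboxypeptidase of the pancreas, at 1312, the amylase gene amy2a at 1202 and the lysosomal membrane gene lamp2 at 1162.

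**Figure D4:**
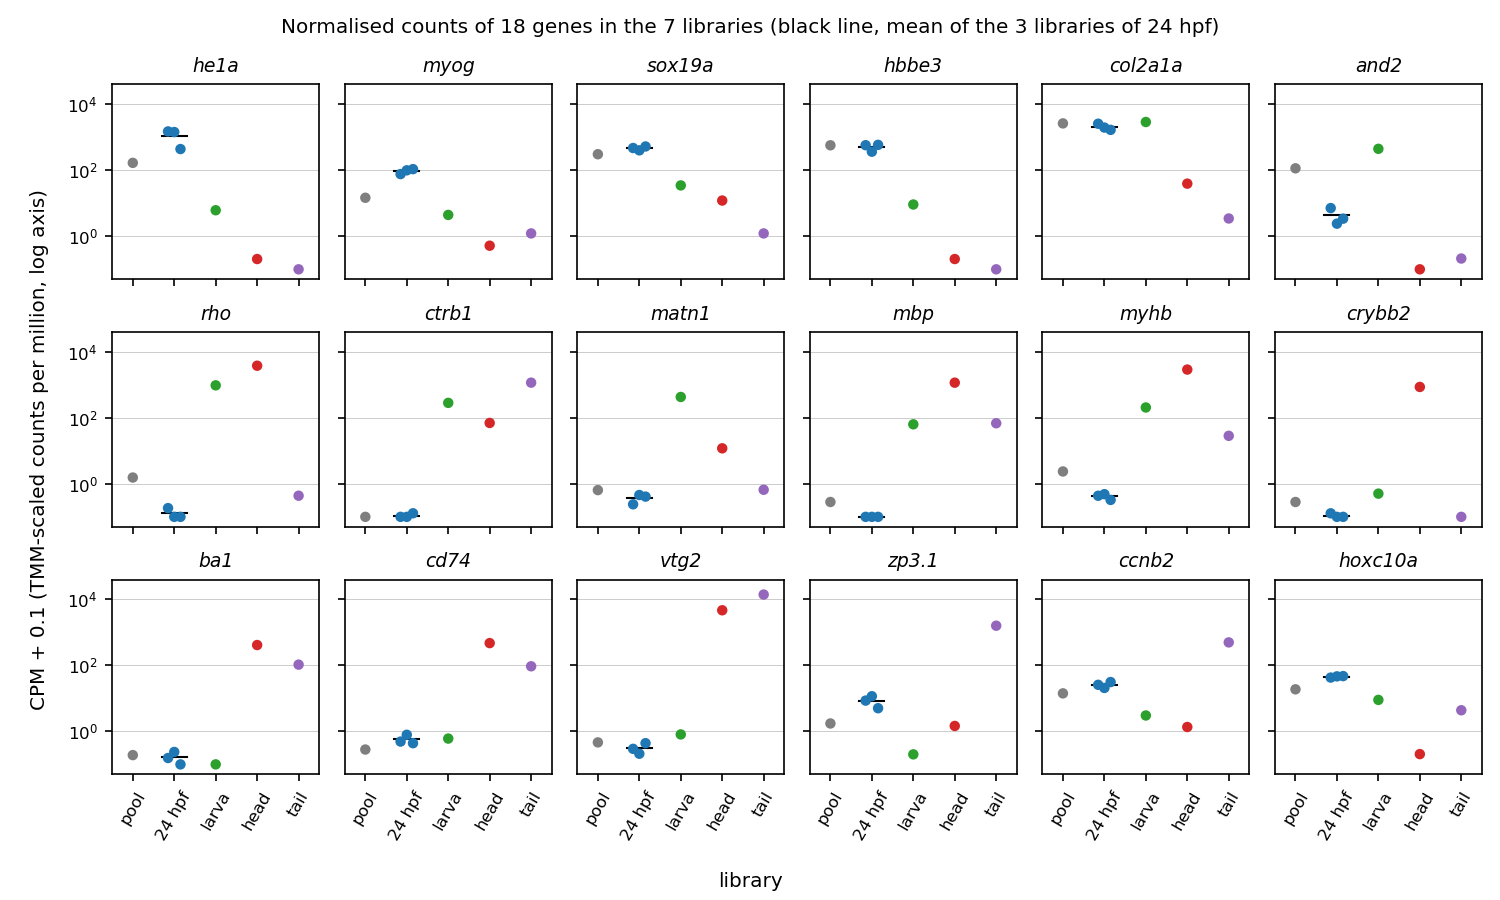
Expression of 18 genes as CPM plus 0.1 on a log axis in each of the 7 libraries, 1 panel per gene and 1 point per library, with a black line at the mean of the 3 libraries of 24 hpf. The rho gene rises to 969 in the larva and 3809 in the head, and vtg2 stands at 4695 in the head and 14052 in the tail.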

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

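Of the alternatives, the refits on genes with the same interval in both annotations were chosen only after the result was seen. The pool has the least stable count of the 4 contrasts with 24 hpf. Over all tested genes, edgeR's quasi-likelihood test called 2509 (6645 at an unadjusted p under 0.05) and limma-voom 3 (5918 at an unadjusted p under 0.05, lowest adjusted p of 0.042). Leaving out 1 library of 24 hpf gave 160 to 4336, while RLE, library totals, DESeq2, no filter, a minimum count of 50, 2 groups only and the older quasi-likelihood method gave 1986 to 2860. For the pool the cause was not tested. Leaving out 1 library gave 8266 to 11810 for the larva, 11402 to 13916 for the head and 9043 to 11859 for the tail. Against a 2-fold change, which is a stricter question, glmTreat called 515 genes for the pool, 6325 for the larva and 7144 for the tail. With the pool joined to the 24 hpf group, 4352 were called for the larva and 6895 for the tail, and with a further 2-fold distance from the pool 6051 remained for the larva. For the joined group the cause was not tested, and a further distance can only remove genes. On the 9964 genes with the same interval, 921, 4808, 6092 and 4840 were called for pool, larva, head and tail, where fewer genes were tested.

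Joining the pool to the 24 hpf group reversed 1 named gene: matn3a (ENSDARG00000069245) in the tail had a log2 change of 3.098 (adjusted p = 0.0157 in edgeR's quasi-likelihood test) and of -1.57 with the joined group (adjusted p = 0.711). Its adjusted p ranged from 0.00514 to 0.711 over all edgeR, DESeq2 and limma-voom alternatives, and the high pool value of 22.02 CPM enters the joined group. Over all pairs of named gene and alternative, the call was kept in 965 of 1289 for the pool, 2511 of 2771 for the larva, 3186 of 3404 for the head and 3259 of 3435 for the tail, and lost in 324, 260, 218 and 175. Most losses in the pool fell in 4 settings: of 105 named genes, limma-voom lost 104, leaving out sample 1 or 2 lost 71 or 70.0, and glmTreat lost 51. No other direction turned. In the comparisons of single libraries, 170.0 of 629 values moved for larva and pool, 151 of 779 for head and tail and 105 of 424 for both adult parts and larva.

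For single libraries the thresholds set the counts. Larva and pool had 1962 genes at least 4-fold apart, 5911 at 2-fold, 732 at 8-fold, 1306 with 2 CPM added, 1071 with a floor of 20 CPM and 1248 in FPKM. Head and tail had 5421, and 10250.0 at 2-fold, 2643 at 8-fold and 3581 with a floor of 20 CPM. Both adult parts against the larva gave 543, and 1750.0 at 2-fold, 240.0 at 8-fold and 313 with a floor of 20 CPM. Enriched genes numbered 530.0 at 8-fold, 1159 at 4-fold and 313 at 16-fold. For FPKM and the added CPM the cause was not tested.

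Of 81 list calls in camera, 0 were left with a correlation estimated per list. There camera's adjusted p ranged from 0.385 to 0.770 among the called lists. A correlation above the preset 0.01 cannot account for every loss. Photoreceptors had estimates of -0.0036 in the larva and 0.0017 in the head, and signalling ligands -0.0093 in both. Other called lists had higher estimates, such as 0.791 for embryonic globins in the larva. What else contributed was not tested. Fry called 55, 28 higher and 27 lower against 34 and 47 in camera, namely 1 for the pool against 11 in camera, 18 against 24 for the larva, 20 against 21 for the head and 16 against 25 for the tail. RLE gave 81, and leaving out 1 library 80 to 81. The median coefficient of variation at 24 hpf was 16.1%, and 17.0% with at least 50 counts or 14.3% in FPKM. No paired analysis was possible because 4 of the 5 groups hold 1 library. Depth limits what absence means: 3 counts correspond to 0.273 CPM in the pool and 0.337 in the tail, but to 0.0279 over the 3 libraries of 24 hpf. Each single library was assumed to vary like the libraries of 24 hpf.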

Other observations

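All 8 tests of explanations described here were chosen only after the result was seen. Of 29 genes of DNA methylation and Polycomb repression, 8 were at least 4-fold higher in head than tail and 9 lower, with a median log2 ratio of -0.23 at percentile 43.2 of random matched lists. Its members went both ways, so the median does not show whether the list differs. The maintenance methyltransferase gene dnmt1 rose from 261 ± 25.7 CPM at 24 hpf to 987 in the tail, a log2 change of 1.92 (adjusted p = 7.01e-04 in edgeR's quasi-likelihood test). It fell to 71.7 CPM in the larva and 23.8 in the head, and on the log2 scale fell by 1.86 and 3.45 (adjusted p = 0.00234 and 1.77e-04 in edgeR's quasi-likelihood test). The de novo methyltransferase gene dnmt3 stood at 117 ± 15.7 CPM at 24 hpf, 9.32 in the larva and 58.0 in the tail, against 3 counts in the head. The Polycomb methyltransferase gene ezh1 rose from 5.79 to 85.1 CPM in the head, and the Polycomb gene CBX7 (2 of 2) from 2.53 to 94.9. In the head 7 of 29 genes of this list were higher and 15 lower (16 lower adjusted over the list alone), with a median of -1.14 (camera adjusted p = 0.0200, and adjusted p = 0.578 with an estimated correlation). The pool had 3 higher, the larva 9 higher and 13 lower, and the tail 8 and 13. Camera did not call the list there (adjusted p = 0.862, 0.1996 and 0.451).

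Heart genes were counted in the adult head library. The atrial myosin gene myh6 rose from 2.44 ± 1.17 to 56.3 CPM and the light chain genes myl7 and cmlc1 from 47.4 to 152 and from 36.0 to 94.3 (adjusted p = 2.70e-04, 0.00213 and 0.00346 in edgeR's quasi-likelihood test). In the tail cmlc1 and the actin gene actc1a fell to 1.24 and 1.69 CPM. Of 16 heart genes 9 were higher and 4 lower in the head (camera adjusted p = 0.379), and 8 were at least 4-fold higher in head than tail. The pigment gene gch2 fell from 307 ± 103 CPM at 24 hpf to 66.9 in the larva, 28.8 in the head and 1.35 in the tail. Pigment cell genes in the head had 4 of 23 higher and 10 lower, haematopoiesis 4 of 18 and 8, and endothelium 8 of 24 and 3 (camera adjusted p = 0.299, 0.187 and 0.338). The replication genes mcm3l and mcm6l, chosen after their values were seen, stood at 325.6 and 280.9 CPM in the tail and at most 2.093 CPM in each other group.

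Vitellogenins in the adult head library lay at a median log2 head to tail ratio of -1.79 over 4 genes. Carry-over of the tail library is argued against by 18 egg coat and germline genes, at a median of -7.86. Liver RNA in the head sample may account for them: 26 liver genes at 100 CPM or more in the tail lay at -1.43, while 16 exocrine pancreas genes lay at -4.18. Whether the dissected head contained liver tissue or its RNA is not given in the sources used here.

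Egg coat and germline genes in the adult tail library may come from oocytes. A list of 15 oocyte genes was drawn up after the tail values were seen, and 10 of them were measured. Of these 10, 9 were at least 8-fold higher in the tail than in every other library, including the meiotic kinase gene wee2 at 191 CPM and NOBOX at 39.5. Among the 9 was also pabpc1l at 403 CPM, already named above among the tail increases, so it is not independent of the pattern. RNA of sperm-forming cells that express flagellum genes is argued against by 10 measured sperm flagellum genes. Each stood at 7.53 CPM or less in the tail, with a median log2 tail to head ratio of -0.0275. Male germ cells without these transcripts were not tested for. An exchange of the head and tail libraries is argued against by 46 of 46 photoreceptor genes at least 4-fold higher in the head. An ovary within the tail sample is therefore a candidate explanation, and the sex of the fish was not used here.

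Among genes at 20 CPM or more at 24 hpf, 22 had 3 counts or fewer in each other library. Conversely, 2 genes at 20 CPM or more in the pool had 3 counts or fewer in each 24 hpf library, whatever the other libraries held. That limit is stricter, since 3 counts are 0.0828 to 0.0847 CPM in a 24 hpf library and 0.273 in the pool. Of the 20 with an FPKM estimate in the pool, 8 were at 1 FPKM or more there, such as ppid at 35.8. For these 8 the counts alone do not show absence from the pool. Presence is not shown either, since an FPKM could include reads shared with other genes. One of the 8, FP016062.1 at 12.2 FPKM, overlaps notch2, which is annotated only in the files of the other libraries. Overlap with a gene annotated only in the files of the other libraries was found for 6 of the 22 (27.3%) and 307 of 7466 others (4.11%), with a one-sided Fisher exact p of 2.15e-04 across genes, which are not independent. For foxd3, whose neighbour is BX664614.1, the FPKM was 18.6 at 24 hpf and 5.56 in the larva despite 0 counts there, so its 0 counts in the larva do not show absence. In the pool its FPKM was 1.45e-04, and overlap and loss of expression cannot be told apart there. A changed gene start or end between the annotations cannot account for the 16 of 22 genes with the same interval. It stays open for the other 6, among them foxd3, ppid and RAC1 (3 of 6). Changed intervals were more frequent among the other genes (4922 of 7466, 65.9%), which does not decide the question for these 6. Changes within an interval were not compared.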
